A study of Caenorhabditis elegans with 4 samples.

How the data were processed

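Binding of SMA-9 was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in hermaphrodite Caenorhabditis elegans at the L2 larval stage. The strain, OP130, carries a transgene in which the sma-9 gene is fused to a tag with TY1, EGFP and FLAG sequences, together with an unc-119 marker, introduced by particle bombardment into unc-119 mutants. Per the labels' protocols, the larvae were crosslinked with formaldehyde, their chromatin was sonicated, and tagged protein was pulled down with anti-GFP antibodies. Input DNA was set aside from the sonicated extract before the pull-down. The 4 libraries comprised 2 ChIP and 2 input libraries, numbered as replicates by the labels. The labels do not say whether the replicates came from separate cultures, so differences between them may be technical.

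The data used here were 3 deposited peak lists, 1 for each ChIP replicate and 1 for the series, called the combined list below. Per the file headers, coordinates are on WormBase build WS220, and the source column of each list names the peak caller PeakSeq. Each peak has a chromosome, a start, an end and a q-value, which is the authors' own value, as deposited, and was used to describe, rank and filter peaks within a list. The highest q-value was 0.00999893 in replicate 1, 0.00972806 in replicate 2 and 0.00994808 in the combined list. The aligner, software versions, threshold, use of the input libraries and the way the combined list was made are not given in the sources used here. Reads, read counts, signal tracks and peak summits were not analysed here, so the depth of each library is unknown, and a difference in the number of peaks cannot be set against a difference in depth. The input libraries had no list here, and no level of background was available to set beside the peaks.

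Peaks were called shared where they overlapped by at least 1 bp. Overlap between the replicates was tested with a one-sided permutation test, in which the replicate 2 peaks of each chromosome were shifted together around that chromosome 100000 times. The smallest p these shifts can give is 1e-05. The q-values of shared and unshared peaks were compared as the difference of median −log10 q with a two-sided permutation test of 100000 resamples. The correlation of −log10 q over shared peaks was tested the same way, and p-values were adjusted by the Benjamini-Hochberg method over these 4 tests. Shares of a list carry exact (Clopper-Pearson) intervals at the 95% level, which cover counting error only. Peaks per chromosome were compared with the chromosome's share of the genome by a two-sided exact binomial test, adjusted over the 6 chromosomes. This test treats peaks as independent, and since listed peaks lay close together its p-values are too small.

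No sequence or chromosome length of the build was used here. The test per chromosome had been planned only for the case that lengths were given, and the span from the chromosome start to the farthest listed peak end in any of the lists was used in their place, 99.9 Mb in all. The gene table at hand was for another assembly, so no peak was assigned to a gene. Planned counts of peaks at promoters, of peaks by annotation class, of peaks near 19 lists of genes and of SMAD sequence motifs were therefore not run, and peaks are named by position.

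The rule for naming peaks was fixed before the data were examined, as were the tests and the alternatives unless stated otherwise. It takes the 20 combined peaks with the lowest q-value among those that overlap a peak in both replicate lists. A few peaks outside this rule were named after their values were seen, and the text says so. Alternatives were an overlap of at least 50% of both peaks, midpoints within 200 bp, peaks within 500 bp of each other, the better-scoring 50% of a list, a q-value of at most 0.001, merging of peaks within 500 bp, other random placements and each replicate list in place of the combined list. The other overlap rules for the named peaks, restriction to peaks of 50 bp or more, exclusion of chromosome I, the comparison of the replicates on chromosome I, the threshold of 1e-10 and all tests of spacing within 5 kb were added after the lists had been seen.

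The overlap test was tried on simulated lists. Of 40 overlaps planted among 89 simulated replicate 2 peaks 40 were found, which checks only the counting, since planted pairs had the same start. With random placement 4 of 100 runs gave a p under 0.05. The simulated peaks were placed uniformly and the widest replicate 1 peak was left out, so the error rate for clustered peaks was not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.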

Results

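SMA-9 is a zinc-finger protein of C. elegans related to Drosophila Schnurri, and a nuclear cofactor of the BMP-like (Sma/Mab) pathway that sets body size and patterns the male tail. To locate its binding regions in L2 larvae, chromatin bound by a SMA-9::GFP fusion was mapped in 2 ChIP replicates. The peak caller listed 517 peaks in replicate 1 and 89 in replicate 2, a ratio of 5.81. The combined list held 960 peaks, 1.86 times as many as replicate 1. Peaks were narrow, with a median width of 151 bp (interquartile range 35 to 287) in replicate 1, 266 bp (150 to 373) in replicate 2 and 144.5 bp (47 to 278) in the combined list. Peaks under 50 bp made up 29.2%, 16.9% and 26.1% of these lists. Together the combined peaks covered 220 kb. No peak had the same start and end in both replicate lists, so these were not copies of a single list. Depth was unknown, and the counts are those of the authors' calls.

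**Figure D1:**
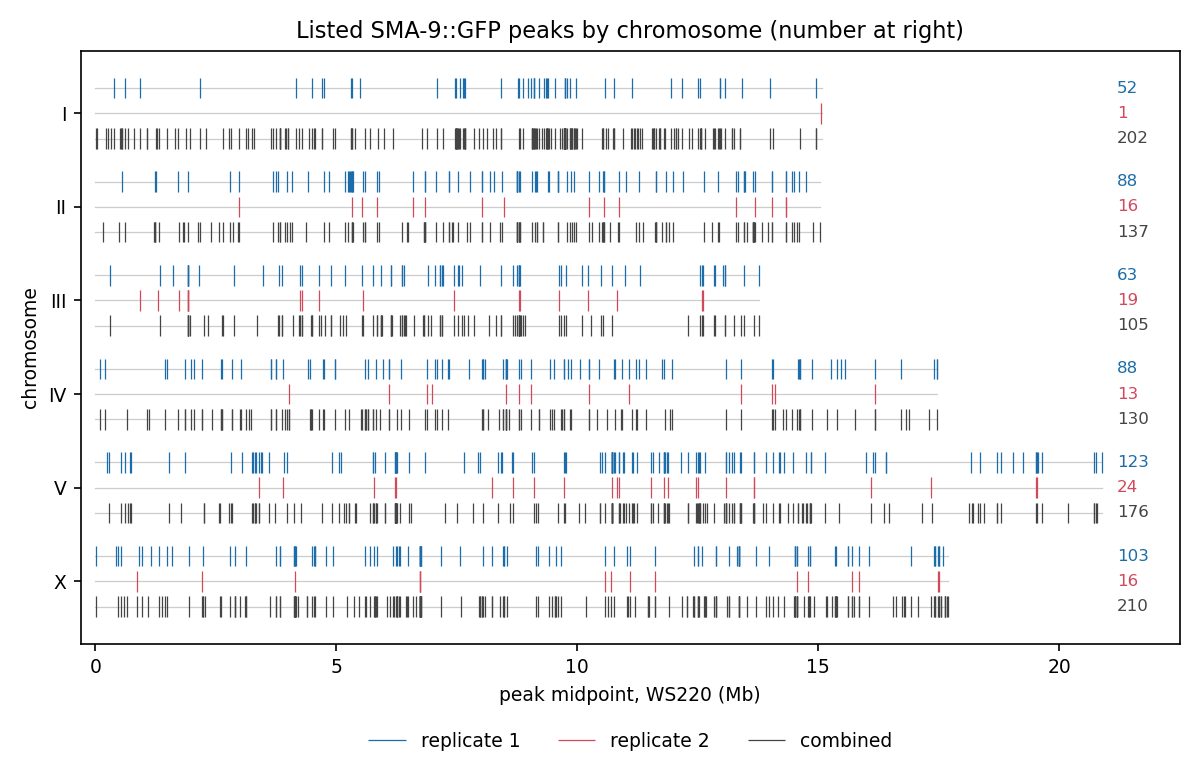
Midpoints of the listed SMA-9::GFP peaks along each chromosome (x axis, position on WS220 in Mb), with a tick per peak in replicate 1 (blue), replicate 2 (red) and the combined list (dark grey) and the number of peaks at the right. Replicate 2 has 1 peak on chromosome I, where replicate 1 has 52 and the combined list has 202.

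Among combined peaks listed in both replicates, the 3 with the lowest q-values lay on chromosome III and the next 2 on X. Among the 20 combined peaks with the lowest q-values of those in both replicate lists, 7 were on III, 7 on X, 3 on V, 2 on II and 1 on IV, and none was on I. Over all 64 such peaks, V had 18, II and III 13 each, X 12 and IV 8. None could lie on I, because the only replicate 2 peak there overlapped no combined peak. The leading peak, III 1924988 to 1925663 (676 bp), had a q of 2.88e-37 in the combined list and ranked 2 there. In the replicate lists it had a q of 3.24e-21 (replicate 1) and 4.61e-15 (replicate 2, rank 1). It lay in a run of 4 peaks from III 1921092 to 1926814 (5723 bp), each of them listed in both replicates. A second member of that run, III 1921092 to 1921727, had a combined q of 2.70e-27, and another, III 1926415 to 1926814, a combined q of 1.27e-14. Elsewhere on III, the peak at 4281898 to 4282715 (818 bp) had a combined q of 1.74e-27, with 2.20e-15 in replicate 1 and 6.83e-14 in replicate 2. The peaks at III 8801492 to 8802315 and III 12612324 to 12612845 followed with 2.01e-17 and 6.73e-16.

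On X, a pair of peaks at 6737323 to 6738052 and 6741534 to 6742481 had combined q-values of 6.31e-20 and 2.14e-18. On V, the strongest peaks listed in both replicates were 6246352 to 6246891 (1.64e-15) and 10717044 to 10717598 (4.66e-14). The peak on IV, 14032803 to 14034533, was the widest of the 20 at 1731 bp, with a q of 1.84e-13. On II the peaks were 14040045 to 14040727 (1.93e-13) and 2973889 to 2974238 (2.71e-13). Across the 20 peaks, combined q-values ran from 2.88e-37 to 7.35e-12 and widths from 350 to 1731 bp. Replicate 2 supported some of them weakly, with q-values up to 0.00759 and ranks down to 66 of 89. In replicate 1 the q-values reached 0.00129 and the ranks 190 of 517. With a stricter rule of 50% overlap of both peaks, 18 of the 20 were still listed in both replicates, and 19 were with midpoints within 200 bp, a pair of alternatives added after the lists had been seen.

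**Figure D2:**
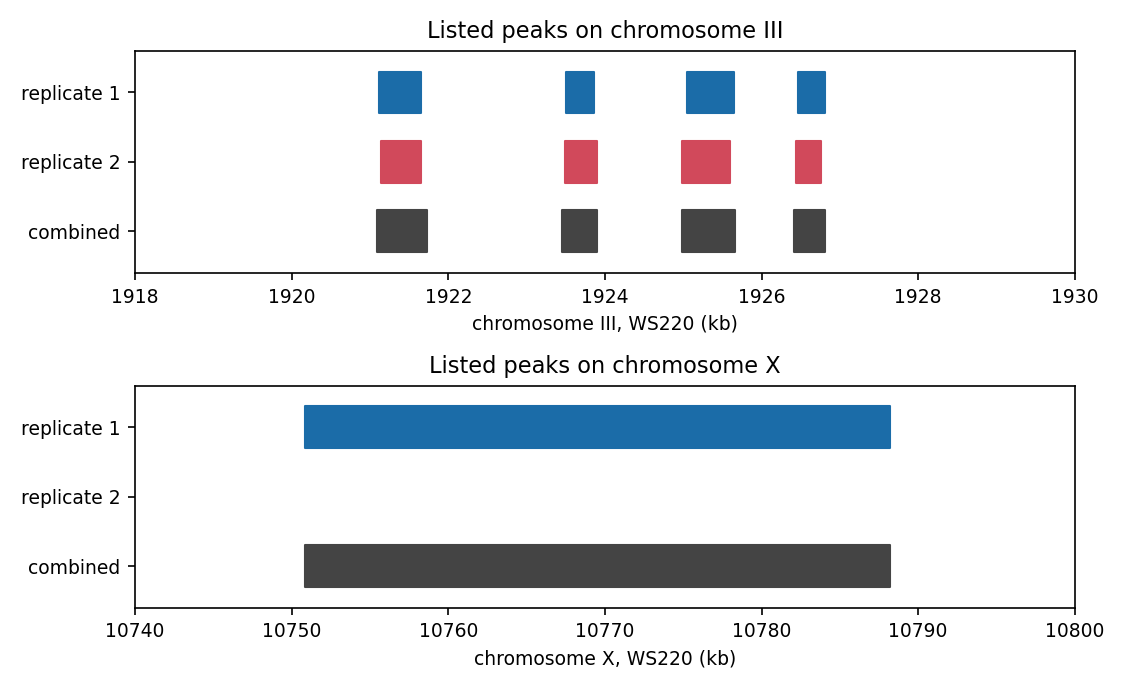
Listed peaks in a pair of regions drawn to scale (x axes, position on WS220 in kb), with a bar per peak in replicate 1 (blue), replicate 2 (red) and the combined list (dark grey). The 4 peaks between 1921092 and 1926814 on III appear in all 3 lists, whereas the peak at 10750843 to 10788222 on X appears in replicate 1 and the combined list and not in replicate 2.

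The peak with the lowest q-value was of another kind and was singled out after its values were seen. It spanned X 10750843 to 10788222, a width of 37380 bp, with a combined q of 1.99e-181. The next widest combined peak measured 1731 bp, and this single region held 16.98% of the base pairs in the combined list. Replicate 1 listed nearly the same interval, 10750877 to 10788183, as its strongest peak with a q of 3.74e-49. Replicate 2 listed 0 peaks inside it, and its nearest peak lay 56471 bp away. The fusion gene is carried as a transgene, and the endogenous sma-9 gene is on X. Whether the region covers it was not determined here, because no annotation of the build was used.

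Most regions found in replicate 2 were also found in replicate 1. Of the 89 replicate 2 peaks, 65 overlapped a replicate 1 peak, or 73.0% (95% interval 62.6 to 81.9). Shifted lists gave 0.269 overlapping peaks on average and 20 at most, so the overlap exceeded chance (one-sided permutation p = 1e-05, the smallest the 100000 shifts can give). Peaks of replicate 1 shared with replicate 2 had lower q-values than the other 452, with a median −log10 q of 4.61 against 2.51 (difference 2.10, permutation p = 1e-05, adjusted 2e-05). They were also wider, at a median of 372 bp against 111 bp. In replicate 2 the medians were 2.70 for the 65 shared peaks and 2.26 for the other 24 (difference 0.439, permutation p = 0.0439, adjusted 0.0439). That difference missed the threshold with a 50% overlap rule (0.307, permutation p = 0.0870), with midpoints within 200 bp (0.247, p = 0.173) and among peaks of 50 bp or more (0.303, p = 0.505), the last an alternative added after the lists had been seen.

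Regions that ranked high in one replicate tended to rank high in the other. Over the 65 shared peaks, −log10 q in the replicates correlated with a Spearman rho of 0.495 (permutation p = 7e-05, adjusted 9.33e-05) and a Pearson r of 0.808 (permutation p = 1e-05, adjusted 2e-05). Without the 2 peaks farthest from the replicate 1 median, Pearson's r was 0.635. The peak at III 4281898 to 4282715, also strong in both replicates, was still included. These correlations are across peaks, which are not independent replicates. The strongest replicate 2 peaks without a partner in replicate 1 were I 15063992 to 15067643, 3652 bp wide and ranked 4 with a q of 1.82e-07, and III 10819934 to 10820023 (8.70e-04). Apart from the wide X region, the strongest replicate 1 peaks without a partner were IV 14594183 to 14594605 (6.82e-12) and IV 8527554 to 8528078 (7.54e-10). These peaks were named after their values were seen.

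**Figure D3:**
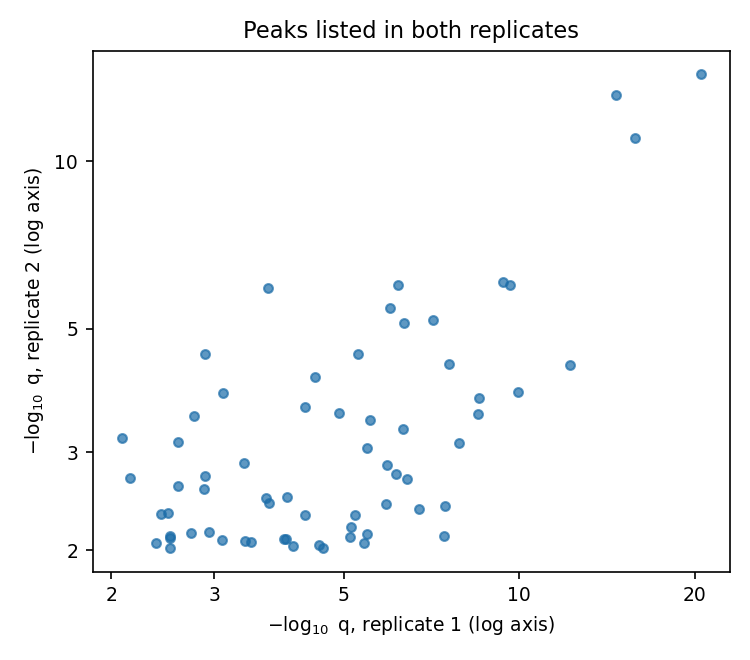
Peaks listed in both replicates, plotted as −log10 q in replicate 1 (x axis) against −log10 q in replicate 2 (y axis), both on log axes, with a point per overlapping pair. The 3 points at the upper right are the peaks on III at 1924988, 4281898 and 1921092, and the Spearman rho over the 65 shared peaks is 0.495.

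Most combined peaks were not listed in either replicate. Of the 960, 382 (39.8%) overlapped a replicate 1 peak and 75 (7.81%) a replicate 2 peak. Both lists held 64 of them, or 6.67% (95% interval 5.17 to 8.43), and 567, or 59.1% (55.9 to 62.2), were in neither. The 64 peaks in both lists had a median q of 5.22e-09 and a median width of 435 bp. The 329 peaks in one list had medians of 2.12e-04 and 213 bp, and the 567 in neither had 0.00205 and 80 bp, with a lowest q of 3.78e-07. Of the better-scoring 480 combined peaks, 63.75% were in at least 1 replicate list and 13.1% in both. In the other direction, 383 of 517 replicate 1 peaks (74.1%, 70.1 to 77.8) and 75 of 89 replicate 2 peaks (84.3%, 75.02 to 91.1) overlapped a combined peak. The 134 replicate 1 peaks that did not had a median width of 23.5 bp, and 95 of them were under 50 bp. No test was made of these shares, since the lists come from the same libraries.

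Chromosomes I and X carried more combined peaks than their spans would give, and III and IV fewer. Chromosome I held 202 peaks, 21.04% of the list (95% interval 18.5 to 23.8), against 145 expected (exact binomial test, adjusted p = 4.88e-06). X held 210, or 21.9%, against 170 expected (exact test, adjusted p = 0.00211). By the same exact test, IV held fewer, 130 against 168 expected (adjusted p = 0.00211), as did III, 105 against 132 (adjusted p = 0.0149). Departures on II (137 peaks, adjusted p = 0.528) and V (176 peaks, adjusted p = 0.0621) did not pass the threshold of the exact test. On I the replicate lists departed the other way: replicate 1 had 52 of 517 peaks, or 10.1% (7.60 to 12.98, exact test, adjusted p = 0.00652), and replicate 2 had 1 of 89, or 1.12% (0.0284 to 6.10, adjusted p = 1.07e-04), both below the 15.1% of its span. On III replicate 2 had 19 peaks, 21.3%, above the 13.8% of its span (exact test, adjusted p = 0.135). Neither replicate list passed the threshold on III, IV or X, where the direction was that of the combined list except for III in replicate 2. The combined list held 3.88 peaks per replicate 1 peak on I and 2.04 on X, against 1.43 to 1.67 on II to V. The excess on X, like that on I, thus came with a higher number of combined peaks per replicate 1 peak.

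Replicate 2 had a lower share of its peaks on chromosome I than replicate 1. The share of peaks there was 8.93 percentage points higher in replicate 1 (Fisher's exact test, two-sided, p = 0.00351, a comparison chosen after the lists had been seen). In the better-scoring 50% of both lists the difference was 7.04 points and missed the threshold (exact p = 0.145). It also missed it at equal list length, where 5 of the strongest 89 replicate 1 peaks and 1 of the 89 replicate 2 peaks were on I (difference 4.49 points, exact p = 0.211, added after the lists had been seen). Among peaks of 50 bp or more the difference passed the threshold (9.03 points, Fisher's exact test, p = 0.0115). It also passed without the single replicate 2 peak on I (10.06 points, Fisher's exact test, p = 3.02e-04), a removal that widens it by construction. These settings were chosen after the lists had been seen. None of the 64 combined peaks in both lists was on I, which follows from the replicate 2 list. Its single peak on I overlaps no combined peak, so the 0 sets no limit on the share of reproducible sites there. At a q of at most 1e-10, a threshold added after the lists had been seen, the combined list held 7 peaks on I and 31 elsewhere. All 38 were in replicate 1. In replicate 2 were 0 of the 7 on I and 27 of the 31 elsewhere. The count of 0 follows from the single replicate 2 peak on I, which overlaps no combined peak. The strongest of those on I were 5311680 to 5312163 (9.83e-15), 7474816 to 7475766 (1.80e-13) and 9381146 to 9381962 (5.92e-13).

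**Figure D4:**
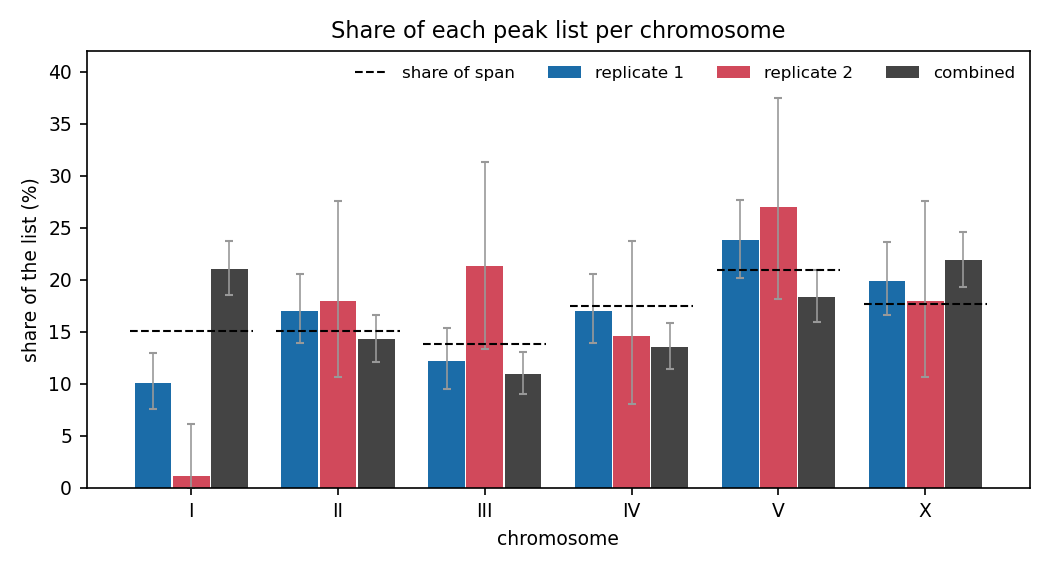
Share of each peak list on each chromosome (bars, in percent, replicate 1 blue, replicate 2 red, combined dark grey), with 95% exact binomial intervals as error bars and the chromosome's share of the summed spans as dashed lines. On I the shares are 10.1%, 1.12% and 21.04% for a span share of 15.1%.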

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

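Settings without chromosome I or with peaks of 50 bp or more, the other overlap rules for the named peaks, and all those for the difference between the replicates on I, were chosen after the lists had been seen. Of 88 alternative values, 49 kept their direction and side of the threshold or, without a test, stayed within the 95% interval of a share or 1.5 times a count. Another 13 moved further, 14 lost the threshold and 12 changed direction, 7 of them on II and V, where no list passed the threshold. The overlap of replicate 2 with replicate 1 stayed above chance in every alternative run, at 62.9% to 86.5% of peaks. The cause of the changes below was not tested, except where a setting removes peaks by its construction.

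The better-scoring 50% of each list left 259, 45 and 480 peaks in replicate 1, replicate 2 and the combined list, and a q of at most 0.001 left 171, 30 and 512. Peaks of 50 bp or more numbered 366, 74 and 709. The share of combined peaks in at least 1 replicate list was 32.2% with 50% overlap, 63.75% in the better-scoring 50%, 46.2% without chromosome I and 44.7% at 50 bp or more. The share in both lists was 13.1%, 8.44% and 8.74% under the last 3 of these. The difference in median −log10 q between shared and unshared replicate 2 peaks was 0.307 with 50% overlap, 0.247 with midpoints within 200 bp and 0.303 at 50 bp or more. The difference between the replicates on I was 7.04 points in the better-scoring 50% of both lists and 4.49 points for the strongest 89 replicate 1 peaks.

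With a single replicate list in place of the combined one, the share on I was 1.12% to 10.1%, on II 17.02% to 17.98%, on III 12.2% to 21.3%, on IV 14.6% to 17.02%, on V 23.8% to 26.97% and on X 17.98% to 19.9%. The excess on I thus became a deficit in both lists, III changed direction in the replicate 2 list and among peaks in both, and II and V went from below to above their share of the span. Among combined peaks in both replicate lists the shares were 0% on I, 20.3% on II and on III, 12.5% on IV, 28.1% on V and 18.75% on X, and at 50 bp or more II had 15.5%. The 0% on I was fixed by the replicate 2 list, whose only peak there overlaps no combined peak. The deficit on III missed the threshold in the better-scoring 50% (11.04%), and that on IV at 50 bp or more (14.7%).

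No paired analysis was possible because the input libraries have no peak list here. Alternatives for promoters, annotation classes, gene lists and motifs were not run. Depth is unknown, so the gap between 517 and 89 peaks cannot be assigned to sequencing or to binding.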

Other observations

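Apart from the share of peaks per chromosome, the tests in this part were chosen after the patterns had been seen in the same lists. SMA-9::GFP peaks came in runs. The combined list held 15 runs of at least 4 peaks less than 5 kb apart, of which 4 were on chromosome I and 10 held a replicate 2 peak. The longest by number were X 6733623 to 6750515, with 11 peaks of which 8 were in replicate 1 and 3 in replicate 2, and I 9733563 to 9747916, with 11 peaks of which 3 were in replicate 1 and 0 in replicate 2. A run on V, 10711702 to 10719876, held 5 peaks, 4 of them in replicate 1 and 1 in replicate 2. In 1 run, III 1921092 to 1926814, all 4 peaks were in both replicate lists. On III, 8795502 to 8802315 held 4 peaks, all in replicate 1 and 2 of them in replicate 2.

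Random spacing was argued against as the whole account of these runs. There were 182 neighbours less than 5 kb apart, against 48.96 on average and 74 at most in 10000 uniform placements (permutation p = 1e-04, the smallest they can give). Wide regions broken into pieces were argued against as well, but only for gaps of up to 500 bp. After peaks within 500 bp were merged, 157 neighbours remained, against 46.5 expected and 75 at most. Pieces with wider gaps between them were not tested, so regions broken in that way stay open. Among the 64 peaks in both replicate lists the count was 6, against 0.256 expected and 3 at most. Neighbours within the run at III 1921092 to 1926814 are part of that count, and peaks within 500 bp were not merged for it. What also stays open is whether uneven chromatin, such as stretches of open promoters where many factors are mapped, may give the same spacing. Uniform placement allows peaks everywhere, and no other factor or input track was analysed here.

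Replicate 2 listed almost no peaks on chromosome I, its 1 peak there lying near the right end, where the ribosomal RNA gene array is. A candidate explanation is that chromosome I was handled differently when the lists were called, because the replicate 1 list fell short of the combined list there too. It had 43 overlaps for 79.6 expected from peaks of like q (permutation p = 1e-05). On X the shortfall was smaller, with 84 for 98.9 expected when I was left out (permutation p = 0.00473). With 52 replicate 1 peaks on I, the expected overlaps there could hardly be reached. The count on I thus restates the low number of replicate 1 peaks there and does not show its cause. Few binding sites on I, a biological explanation, stay open, since the combined share was 21.04% for 15.1% of the span while both replicate lists lay below it, at 10.1% and 1.12%. A replicate 2 weaker on all chromosomes alike was not settled by the strongest 89 replicate 1 peaks. Their share on I was 4.49 points higher than that of replicate 2 (Fisher's exact test, p = 0.211). Combined peaks at a q of at most 1e-10, a threshold added after the lists had been seen, did not settle it either. Replicate 2 listed 27 of 31 elsewhere and 0 of 7 on I. The 0 follows from the single replicate 2 peak on I, which overlaps no other listed peak, and so restates the pattern. Peaks of like combined q may also be unlike in strength. On I the combined −log10 q ran further above that of replicate 1 than elsewhere, as given below. Absence of replicate 2 signal on I cannot be told apart from such handling.

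The test that bears on that absence took the 43 combined peaks on I listed in replicate 1 and not in replicate 2. Their gain in −log10 q from replicate 1 to the combined list had a mean percentile rank of 78.2, for 50.7 expected from peaks of like replicate 1 q (permutation p = 1e-05), but a low call rate in replicate 1 would raise it too, and q-values of separate lists share no stated scale. The rank was chosen after a first version on the mean gain had missed the threshold, at 2.90 for 1.75 expected (permutation p = 0.158), while the mean without the wide X region, whose gain was 132, gave 1.27 expected (permutation p = 1e-05).

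The wide X region, listed in replicate 1 and the combined list, is of a size that a large-insert transgene could have, and a candidate explanation is extra copies of the transgene DNA in the chromatin. That stays open: replicate 2, from the same strain, had no peak within 56471 bp, but its list may not follow the signal there, and no input track was analysed here to show copy number. Lack of replicate 2 signal in the region was examined against 274 other peaks off chromosome I that only replicate 1 listed, 71 of them on X. The region's ratio of combined to replicate 1 −log10 q was 3.73, against 2.75 at most among them. Its gain was 132, against 4.09 at most. On I, 1 of the 43 peaks that only replicate 1 listed, 7474816 to 7475766, had a higher ratio, 4.53, over a weak replicate 1 q of 0.00154. Whether replicate 2 signal was absent on I is itself unsettled, so that peak cannot show what such a lack would give. A ratio as high as that of the region also occurred with replicate 2 support, since the highest among peaks in both lists was 3.85. Over the 64 peaks in both lists, the combined −log10 q lay near the sum of the replicate values. The median difference from that sum was 0.405 (interquartile range −0.502 to 1.69), and the highest gain over replicate 1 was 16.05. Lack of replicate 2 signal was left open, because the 274 peaks reached only 1493 bp and a replicate 1 −log10 q of 11.2, against 48.4 for the region. How the combined q-values were made is also not given in the sources used here.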
